A study of Mus musculus with 6 samples.

How the data were processed

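Gene expression was measured by RNA-seq in 6 libraries of mouse Th17 cultures, 3 grown with the vehicle DMSO and 3 with oligomycin. Per the labels' protocols, RNA was isolated on RNeasy Plus Mini columns and libraries were made by Illumina's procedure. The deposited values are FPKM (fragments per kilobase of transcript, scaled to the mapped fragments of a library), 1 value per gene and library, as the deposited column names and the submitters' processing notes show. Those notes name TopHat2 2.1.0, Cufflinks 2.2.1.0, Cuffnorm 2.2.1.1 and Cuffdiff 2.2.1.3, with the mouse build GRCm38 (mm10). What each tool did, the annotation, the scaling between libraries, the filters, the handling of reads with several matches, the strand of the libraries and whether RNA was selected by its poly(A) tail are not given in the sources used here. Because FPKM are already divided by transcript length and library size, no count model was used.

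The deposited table held 10041 rows, each with a gene symbol, a locus and the quantification status OK, and the lowest mean in the higher of both groups was 1.4993 FPKM. 122 rows named several genes, 1187 rows shared a locus with another row, 182 were small RNA rows (such as microRNA and snoRNA rows) and 55 were histone rows. No row lay on the mitochondrial chromosome, so mitochondrially encoded genes are not analysed here. Gene names were used as the table gives them; starts were read as counted from 0, because adding 1 matched the GENCODE M21 start of 3636 of 9019 symbols, against 487 without it, and they are printed counted from 1. Columns carried the group and a number from 1 to 3, which does not occur in the sample titles, so each column was mapped to its group only. Replicate numbers given here are those column numbers.

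Sequencing depth is unknown, since the low values of a library showed no common step from which whole reads could be recovered, so no counting interval is given. The FPKM sums of the libraries ran from 1434028 to 2103404, of which small RNA rows took 71.1% to 82.2%. As FPKM are divided by transcript length, which is short for these rows, this is not their share of the reads. Without the small RNA rows the sums ran from 368095 to 423072, with medians over all rows from 13.8 to 14.7 FPKM.

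Values were tested as log2(FPKM + 1) with limma 3.58.1 (R 4.3.3), using moderated statistics with an intensity trend, a model with the group alone, 2-sided p-values and Benjamini-Hochberg adjustment over all genes tested. The pseudocount of 1 understates the change of genes with low values. Genes with an FPKM of at least 1 in at least 3 of the 6 libraries were tested, which left 9986 of 10041 rows, and a gene was called where its adjusted p lay under 0.05. Errors are SD over 3 libraries per group or the SE of the fitted log2 change, and fold values are ratios of the group means in FPKM. In a simulation built on these libraries, in which 9945 genes were tested, the procedure called 66 of 100 genes changed by 1 on the log2 scale, 6 of 100 changed by 0.5 and 9 of 9733 left unchanged. A list shifted by 0.8 was called there and 0 other lists were. Genes were drawn independently in the simulation, while correlations estimated in these libraries reached 0.622 (cell cycle list). The simulation therefore cannot show how often lists of correlated genes are called without a shift. Far fewer genes were changed in it than were called in the data (3013 of 9986), and the adjustment is stricter where few genes change. The simulated shares therefore do not tell which part of the real changes of 1 or 0.5 was called.

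Before the data were examined, the main test, its alternatives, 27 gene lists for processes of the cell, 5 lists of markers of other cells and the rule for named genes were fixed. 26 lists had at least 5 tested genes and were tested with limma's camera (preset correlation of 0.01, adjusted over the lists), which compares a list with all other genes; fry was run in addition and tests whether a list's genes move, on balance, one way. Camera was also run with a correlation estimated for each list. 2 lists had fewer tested genes and are described by their values, and 4 had none in the table. For each list the number of called genes is given as adjusted over all genes tested and as adjusted over the list alone.

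The rule for the genes the text names took the 12 largest rises and the 12 largest falls in log2(FPKM + 1) among genes with an adjusted p under 0.05, a mean of at least 5 FPKM in the higher group and the same direction in every pair of libraries; as the title numbers are on no column, this last part was taken as groups that do not overlap, which holds for any pairing and gave the same 24 genes as pairs by column number. It added, among others, Il17a, Il17f, Il23r, Foxp3, Batf, Csf2, Ifng, Il2, Il10 and Myc, and the 4 tested members with the smallest p of each list described, with members needed for a range. The following names lie outside it and were chosen after their values were seen: Runx1, Il21, Ccl20, Il1r1, Slc2a1, Ldha, Hk2, Pkm, Atf4, Ddit3, Mki67, Top2a, Tcf7 and Egr2, and, to name the members behind counts of 5 or fewer, Nt5e, Entpd1, Id3, Ndufa6, Ndufb4, Atp5l, Vldlr, Manf, Pdia6, Xbp1 and Echs1. The histone, kinesin, centromere protein, zinc finger and other gene families and the members named for them were also chosen then.

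Alternatives changed 1 choice at a time: a pseudocount of 0.1, no filter on low values, a minimum of 5 FPKM, median-ratio rescaling, quantile normalization, no intensity trend, each of the 6 libraries left out in turn, and camera with an estimated correlation. 5 more were added after the data were seen: the column number as a block, leaving out small RNA rows, leaving out rows that share a locus or name several genes, scaling to equal FPKM sums over rows other than small RNA and histone rows, and testing the lists without cell cycle and histone rows. The planned block on the title numbers could not be fitted, and the planned count models were not run because the table holds no counts. Rows of near-identical copies (ribosomal protein and histone genes in particular, which have many pseudogenes or paralogs), overlapping genes and antisense partners carry the uncertainty that reads cannot be told apart between them. Nothing in the labels says that the libraries of a group came from separate cultures or animals, so the p-values measure only the spread between these samples, which may be technical.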

Results

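Transcript levels were compared between mouse Th17 cultures grown with oligomycin (2.5 ng/ml), which blocks the mitochondrial ATP synthase and with it oxidative phosphorylation, and cultures grown with the vehicle DMSO, in 3 libraries each. All cells started as naive CD4 T cells and spent 48 h on plates coated with anti-CD3e (10 µg/ml), with anti-CD28 (1 µg/ml), IL-6 (20 ng/ml), TGF-β1 (2.5 ng/ml) and IL-23 (10 ng/ml). Such conditions turn naive cells into Th17 cells, the helper T cells that secrete IL-17. The comparison asks how the Th17 transcriptome depends on mitochondrial oxidative phosphorylation. Expression was given as FPKM for 10041 rows, and the sequencing depth behind the values is unknown. Pearson correlations of log2(FPKM + 1) across the tested genes, which are not independent replicates, ran from 0.963 to 0.969 within DMSO and from 0.940 to 0.962 within oligomycin. Between the groups they ran from 0.890 to 0.937. Small RNA rows took 71.1%, 78.0% and 77.7% of the FPKM sum in the DMSO libraries and 80.8%, 82.2% and 80.2% in the oligomycin libraries. Division by transcript length raises the FPKM of short transcripts, so these are not shares of reads or of RNA.

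Cultures grown with oligomycin held far less mRNA for IL-17A and for enzymes that make unsaturated fatty acids, and less for glycolysis, cholesterol synthesis and cell division. They held more mRNA for the amino acid stress response, ribosomal proteins and several genes of resting T cells. These levels are relative to the other transcripts of a library, since FPKM do not measure amounts per cell. Il17a, the gene of the signature Th17 cytokine, averaged 247 ± 15.4 FPKM (SD, n = 3) with DMSO and 12.5 ± 2.45 (n = 3) with oligomycin, a 19.6-fold lower mean. Of 9986 genes tested with limma, 3013 (30.2%) passed an adjusted p of 0.05, 1403 of them higher and 1610 lower with oligomycin. Without DMSO replicate 1 the count was 1887 (816 higher, 1071 lower) and without DMSO replicate 3 it was 1769 (780 higher, 989 lower). Without DMSO replicate 2 the lower genes numbered 1040.

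Of 21 tested genes of the Th17 list 7 fell, the genes of both IL-17 cytokines among them, 2 rose and 12 were not called (9 fell and 2 rose when adjusted over the list alone). The list did not pass the camera test (adjusted p = 0.0577, and adjusted p = 0.667 with an estimated correlation). Il17a (XLOC_000035, chromosome 1, 20730905 to 20734496, GRCm38) fell by 4.21 on the log2 scale (SE 0.14, adjusted p = 2.44e-06). Il17f (XLOC_000676, chromosome 1, 20777146 to 20784270), which encodes a related cytokine, fell by 2.33 (SE 0.20, adjusted p = 0.000128), from 1469.7 ± 129 to 297 ± 75.5 FPKM. Il23r, the receptor subunit through which IL-23 sustains Th17 cells, fell from 5.70 ± 2.23 to 0.454 ± 0.0671 FPKM (adjusted p = 0.000507). Ccr6, a chemokine receptor of Th17 cells, dropped from 20.6 ± 4.30 to 4.23 ± 1.08 FPKM (adjusted p = 0.000229), and its ligand gene Ccl20 from 79.1 ± 15.7 to 39.9 ± 8.58 (adjusted p = 0.00758). Il1r1, a receptor for IL-1, fell from 8.78 ± 4.40 to 1.1 ± 0.390 FPKM (adjusted p = 0.00339). Il21, a cytokine that acts back on Th17 cells, fell from 156 ± 10.0 to 78.5 ± 27 FPKM (adjusted p = 0.00981). Maf and Runx1, transcription factors that act in Th17 cells, rose, Maf from 91.3 ± 14.8 to 161 ± 23.2 FPKM (adjusted p = 0.00732) and Runx1 from 11.4 ± 1.74 to 18.9 ± 2.02 (adjusted p = 0.0089). Batf, the gene of a transcription factor needed for the lineage, stood at 98.8 ± 21.8 and 101 ± 13.4 FPKM (log2 change 0.04, adjusted p = 0.866). Il10, the gene of an anti-inflammatory cytokine, stood at 23.6 ± 9.05 and 24.4 ± 1.16 FPKM (adjusted p = 0.734). The log2 change of Batf was -0.14 without DMSO replicate 1 and -0.06 without oligomycin replicate 1, and that of Il10 was -0.12 without DMSO replicate 1.

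**Figure D1:**
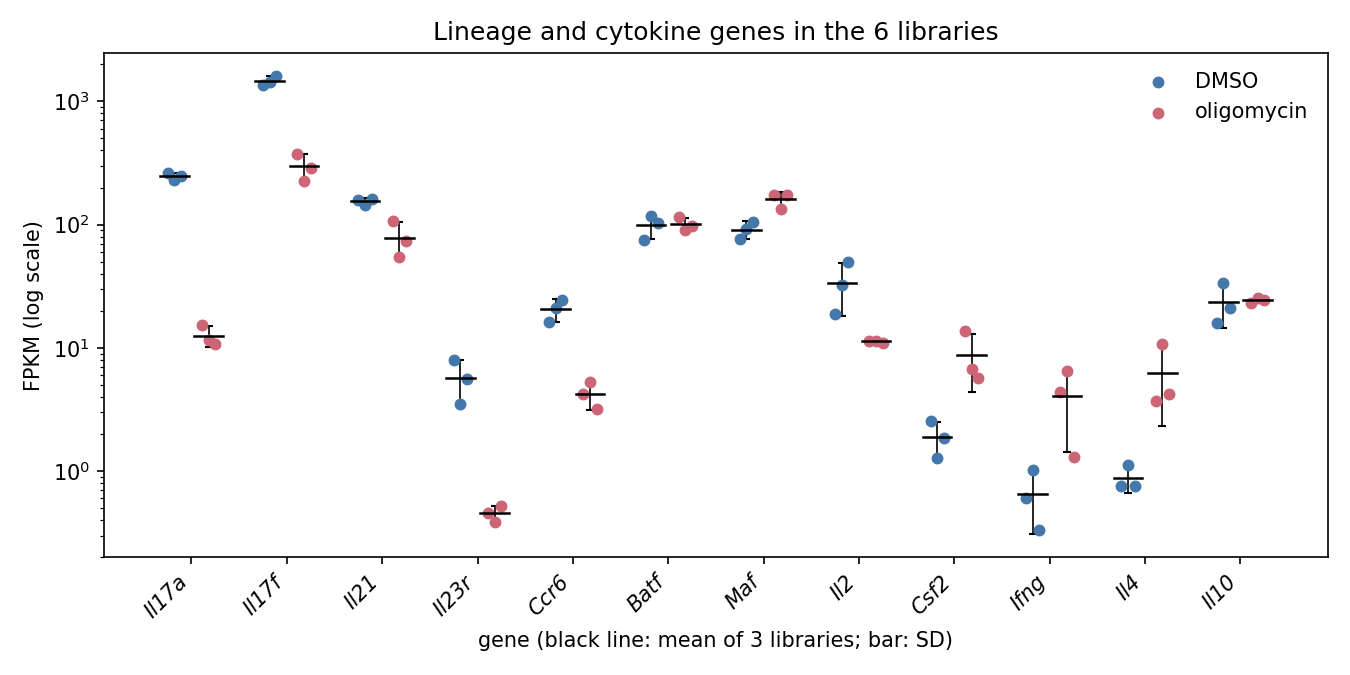
FPKM (log scale) of 12 lineage and cytokine genes in the 6 libraries; points are libraries, black lines the means of 3 libraries and bars the SD. Il17a lay at 230.4 to 261 FPKM with DMSO and at 10.8 to 15.4 with oligomycin, while Batf averaged 98.8 and 101.

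The Th17 list had a median log2 change of -0.14 and a mean of -0.73. It passed camera without DMSO replicate 1 (adjusted p = 0.0104) and without oligomycin replicate 1 (adjusted p = 0.0494), and its median was 0.01 without DMSO replicate 2. Without any 1 of the DMSO libraries Il23r was too low to be tested, so the list lacked it there. In the signature of pathogenic Th17 cells, 1 of 12 genes rose and 3 fell (2 and 4 adjusted over the list alone; camera adjusted p = 0.638). Csf2, which encodes the inflammatory cytokine GM-CSF, rose from 1.89 ± 0.629 to 8.68 ± 4.28 FPKM (adjusted p = 0.00404). Gzmb, which encodes a protease of cytotoxic granules, Icos, a costimulatory receptor, and Stat4, a signal transducer of IL-12 and IL-23, fell, with log2 changes of -1.29, -1.20 and -1.14. The median of that signature, -0.10, was 0.01 without DMSO replicate 2 and 0.06 without oligomycin replicate 3, and 2 of its genes rose without DMSO replicate 1 or oligomycin replicate 2. In the non-pathogenic signature 3 of 7 genes rose (Maf, Il6st and Ikzf3) and 1 fell (Il1rn), the same counts as adjusted over the list alone (camera adjusted p = 0.293). Without DMSO replicate 1 its median was -0.07, against 0.11 with all libraries, and 2 genes fell.

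Genes of the Th1 and Th2 lineages moved in both directions. Il4 and Ifng, the main cytokines of Th2 and Th1 cells, rose from low levels, Il4 from 0.878 ± 0.207 to 6.21 ± 3.91 FPKM (adjusted p = 0.00428) and Ifng from 0.656 ± 0.350 to 4.05 ± 2.60 (adjusted p = 0.0243). The call of Ifng was lost without DMSO replicate 1 (adjusted p = 0.0653), DMSO replicate 3 (0.0789), oligomycin replicate 1 (0.0574) or oligomycin replicate 2 (0.0558). Il12rb2, a subunit of the IL-12 receptor, fell from 11.6 ± 6.23 to 1.52 ± 0.292 FPKM (adjusted p = 0.00112). Ccr4, a chemokine receptor of Th2 cells, fell from 52.1 ± 2.68 to 14.4 ± 1.25 FPKM (adjusted p = 4.23e-05). In the Th1 list 1 of 10 genes rose (Ifng) and 4 fell (1 and 5 adjusted over the list alone; camera adjusted p = 0.212). Il12rb2, Stat4 and the transcription factor gene Runx3 (log2 change -0.96) were among those that fell. In the Th2 list Il4 and Areg, the gene of the growth factor amphiregulin, rose and Ccr4 fell among 7 genes (2 and 2 adjusted over the list alone; camera adjusted p = 0.968). Its median log2 change was 0.37 and its mean 0.13, but the camera test pointed down. The median was -0.09, -0.50 and -0.31 without oligomycin replicate 1, 2 or 3, with 1 gene rising in each case and 2 falling without replicate 2. Areg was too low to be tested in these settings. Its rise was thus not tested there, and these medians leave it out.

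Genes shared with regulatory T cells included some of the more abundant transcripts that fell. Ctla4, an inhibitory receptor, dropped from 575 ± 31.5 to 102 ± 37.2 FPKM (adjusted p = 0.000215). Tnfrsf4 and Tnfrsf18, costimulatory receptors of the TNF receptor family, dropped from 277 ± 47.4 to 95.5 ± 12.5 and from 219.7 ± 53.2 to 62.5 ± 16.6 FPKM. Il2ra, the high-affinity subunit of the IL-2 receptor, fell by 0.81 (adjusted p = 0.00817), and Il2 itself went from 33.6 ± 15.4 to 11.3 ± 0.241 FPKM (adjusted p = 0.00805). Of 13 genes of the regulatory T cell list, 2 rose and 4 fell, also when adjusted over the list alone (camera adjusted p = 0.293). Those that rose were Nt5e and Entpd1, ectoenzymes that turn extracellular ATP into adenosine, with means 1.89-fold and 1.92-fold higher. Entpd1 was not called without any library other than oligomycin replicate 2 (adjusted p between 0.0517 and 0.138), nor with all libraries under quantile normalization (0.0727). Foxp3, the gene of the regulatory T cell master regulator, appeared only in a row combined with 4930524L23Rik, at 8.63 ± 5.96 and 12.5 ± 2.50 FPKM (adjusted p = 0.267).

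Glycolytic genes and targets of HIF-1, the transcription factor of the hypoxia response, were lower with oligomycin. Of 18 tested glycolysis genes 16 fell and 0 rose in the limma test, and 16 fell when adjusted over the list alone. Their median log2 change was -1.07 (camera adjusted p = 1.28e-09, and adjusted p = 0.341 with an estimated correlation). Slc2a3 and Slc2a1, which encode glucose transporters, fell from 41.7 ± 7.49 to 9.72 ± 0.920 FPKM (adjusted p = 7.78e-05) and from 138 ± 14.3 to 60.3 ± 9.26 (adjusted p = 0.000779). Slc16a3, which encodes a lactate exporter, fell by 2.50 (adjusted p = 0.000194), Aldoc, an aldolase, by 2.60 and Tpi1, a triosephosphate isomerase, by 1.68. Hexokinase 2 (Hk2), lactate dehydrogenase A (Ldha) and pyruvate kinase (Pkm) had means 1.93-fold, 2.11-fold and 1.80-fold lower. In the HIF-1 list 16 of 20 genes fell and 0 rose, and 16 fell when adjusted over the list alone. The median there was -0.95 (camera adjusted p = 1.32e-07, and adjusted p = 0.336 with an estimated correlation). Bnip3, a mitophagy receptor, fell from 40.3 ± 3.76 to 5.98 ± 1.89 FPKM (adjusted p = 7.23e-05), and P4ha2 (collagen prolyl hydroxylase), Ankrd37 and Ddit4 (an inhibitor of mTORC1) fell by 1.84, 1.22 and 1.21.

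Among 80 nuclear genes of the OXPHOS complexes 15 fell, 4 rose and 61 were not called (12 fell and 3 rose adjusted over the list alone), against 16.1% and 14% of all tested genes that fell and rose. Their median log2 change was -0.26 (camera adjusted p = 0.000963, and adjusted p = 0.69 with an estimated correlation). Relative to the mean of the 6 libraries, the mean log2 level of the list was 0.06 in oligomycin replicate 1, inside the DMSO range (0.06 to 0.14), and -0.25 and -0.16 in replicates 2 and 3. Atp5g3, a subunit of the ATP synthase, fell from 449.5 ± 13.3 to 249 ± 47.5 FPKM (adjusted p = 0.00483), and Cyc1 (cytochrome c1) from 92.2 ± 2.25 to 56.8 ± 9.41 (adjusted p = 0.00663). Ndufb8, a complex I subunit, fell from 222 ± 12.8 to 146 ± 11.9 FPKM (adjusted p = 0.00782). Cox7a2l, a factor of respiratory supercomplexes, rose from 89.2 ± 1.39 to 150.3 ± 11.2 FPKM (adjusted p = 0.00207). The others that rose were Ndufa6 and Ndufb4 of complex I and Atp5l of the ATP synthase (log2 changes of 0.55, 0.66 and 0.56). Ndufa6 was not called without DMSO replicate 3 (adjusted p = 0.0597). Ndufb4 was not called without DMSO replicate 1 or 2 or oligomycin replicate 1 or 3 (adjusted p = 0.0602, 0.0857, 0.0744 and 0.0969), nor Atp5l without DMSO replicate 1 or 3 or oligomycin replicate 1, 2 or 3 (0.139, 0.151, 0.0673, 0.111 and 0.0549). The number that fell was 9, 7 and 7 without DMSO replicates 1, 2 and 3 and 32, 9 and 7 without oligomycin replicates 1, 2 and 3, and 2 rose without DMSO replicate 1, DMSO replicate 3 or oligomycin replicate 3. The median was -0.17 without oligomycin replicate 2, and the list call was lost under quantile normalization (adjusted p = 0.178).

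In the mitochondrial ribosome 8 of 73 genes fell and 3 rose (5 and 3 adjusted over the list alone), both smaller shares than among all tested genes. The median log2 change was -0.20 (camera adjusted p = 0.0148, and adjusted p = 0.69 with an estimated correlation). The mean log2 level relative to the 6 libraries was 0.09 in oligomycin replicate 1, inside the DMSO range (0.06 to 0.11), and -0.22 and -0.13 in replicates 2 and 3. The genes that rose were Mrps5, Mrpl24 and Mrpl52, by 0.68, 0.59 and 0.71. The list call was lost under quantile normalization (adjusted p = 0.182) and without oligomycin replicate 2 (median -0.12, adjusted p = 0.192). The number that fell was 4, 3 and 2 without DMSO replicates 1, 2 and 3, 15 without oligomycin replicate 1 and 3 without oligomycin replicate 3.

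Of the mitochondrial fuel pathways, fatty acid oxidation had 8 of 17 genes that fell and 2 that rose, also when adjusted over the list alone. Its median log2 change was -0.35 (camera adjusted p = 0.0318, and adjusted p = 0.594 with an estimated correlation). Acadl and Acadm, acyl-CoA dehydrogenases, and Acaa2, a thiolase, had means 2.28-fold, 1.75-fold and 1.67-fold lower. Eci1, which isomerizes unsaturated intermediates, rose from 12.4 ± 2.29 to 23.4 ± 3.22 FPKM (adjusted p = 0.00577). Echs1, a hydratase, rose by 0.42 but was not called without DMSO replicate 2 or 3 or oligomycin replicate 2 or 3 (adjusted p = 0.0972, 0.0846, 0.0555 and 0.0588), which left 1 rising gene. The list lost its call when rows sharing a locus were left out (adjusted p = 0.0555), without DMSO replicate 1 (0.0669) and without oligomycin replicate 2 (0.0632), and 5 genes fell without DMSO replicate 1, 2 or 3 and 4 without oligomycin replicate 3. In the TCA cycle 3 of 15 genes fell and 0 rose (2 and 0 adjusted over the list alone), with a median of -0.27 (camera adjusted p = 0.0367, and adjusted p = 0.641 with an estimated correlation). Among those that fell, Sucla2, of succinyl-CoA ligase, was not called without DMSO replicate 1 or 3 (adjusted p = 0.0649 and 0.0674). Idh3b, of isocitrate dehydrogenase, was not called without any library other than oligomycin replicate 2 (adjusted p between 0.0592 and 0.157). With all libraries the call of Idh3b was lost with no filter (0.0506), a minimum of 5 FPKM (0.0503), quantile normalization (0.179) or no intensity trend (0.0602). The TCA list call was lost with a minimum of 5 FPKM (adjusted p = 0.0557), under quantile normalization (0.221), without rows sharing a locus (0.15), and without DMSO replicate 1 (0.0814), oligomycin replicate 2 (0.0894) or oligomycin replicate 3 (0.0825). In that list 1 gene fell without DMSO replicate 1 or 3 and 6 without oligomycin replicate 1.

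Lipid synthesis held the steepest fall. Scd1 (XLOC_010506, chromosome 19, 44394450 to 44407709), the desaturase that makes monounsaturated fatty acids, averaged 33.5 ± 2.13 FPKM with DMSO and 0.152 ± 0.0969 with oligomycin. Its log2 change of -4.91 (SE 0.13, adjusted p = 8.0e-07) was the largest fall with a pseudocount of 1. Fads2, a desaturase of polyunsaturated fatty acids, averaged 20.4 ± 0.592 FPKM with DMSO and was listed at 0.406, 0 and 0.322 FPKM in the oligomycin libraries (adjusted p = 5.35e-06). A row combining Scd2, a further desaturase, with the microRNA gene Mir5114 dropped from 303 ± 18.5 to 18.8 ± 5.71 FPKM (adjusted p = 2.13e-05). Elovl6, an elongase of saturated chains, and Fads1 fell by 1.87 and 1.02. In the fatty acid synthesis list 7 of 11 genes fell and 0 rose, also when adjusted over the list alone, and 4 fell without DMSO replicate 2 or DMSO replicate 3. Its median log2 change was -0.68 (camera adjusted p = 6.88e-06, and adjusted p = 0.194 with an estimated correlation). Cholesterol synthesis fell across the pathway, with 17 of 23 genes lower and 0 higher (20 and 0 adjusted over the list alone). The median there was -0.76 (camera adjusted p = 6.7e-10, and adjusted p = 0.278 with an estimated correlation). Fdps, a prenyl transferase, fell from 53.3 ± 5.37 to 15.2 ± 3.11 FPKM (adjusted p = 0.000186) and Pmvk, a kinase of the mevalonate route, from 46.0 ± 3.47 to 17.6 ± 1.31 (adjusted p = 0.000128). Stard4, a cholesterol carrier, fell from 26.7 ± 3.96 to 8.75 ± 1.5 FPKM (adjusted p = 0.00032). Scd1, Fads2 and other genes at 1 FPKM or more in the 3 libraries of 1 group alone could not be tested without a library of that group.

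**Figure D2:**
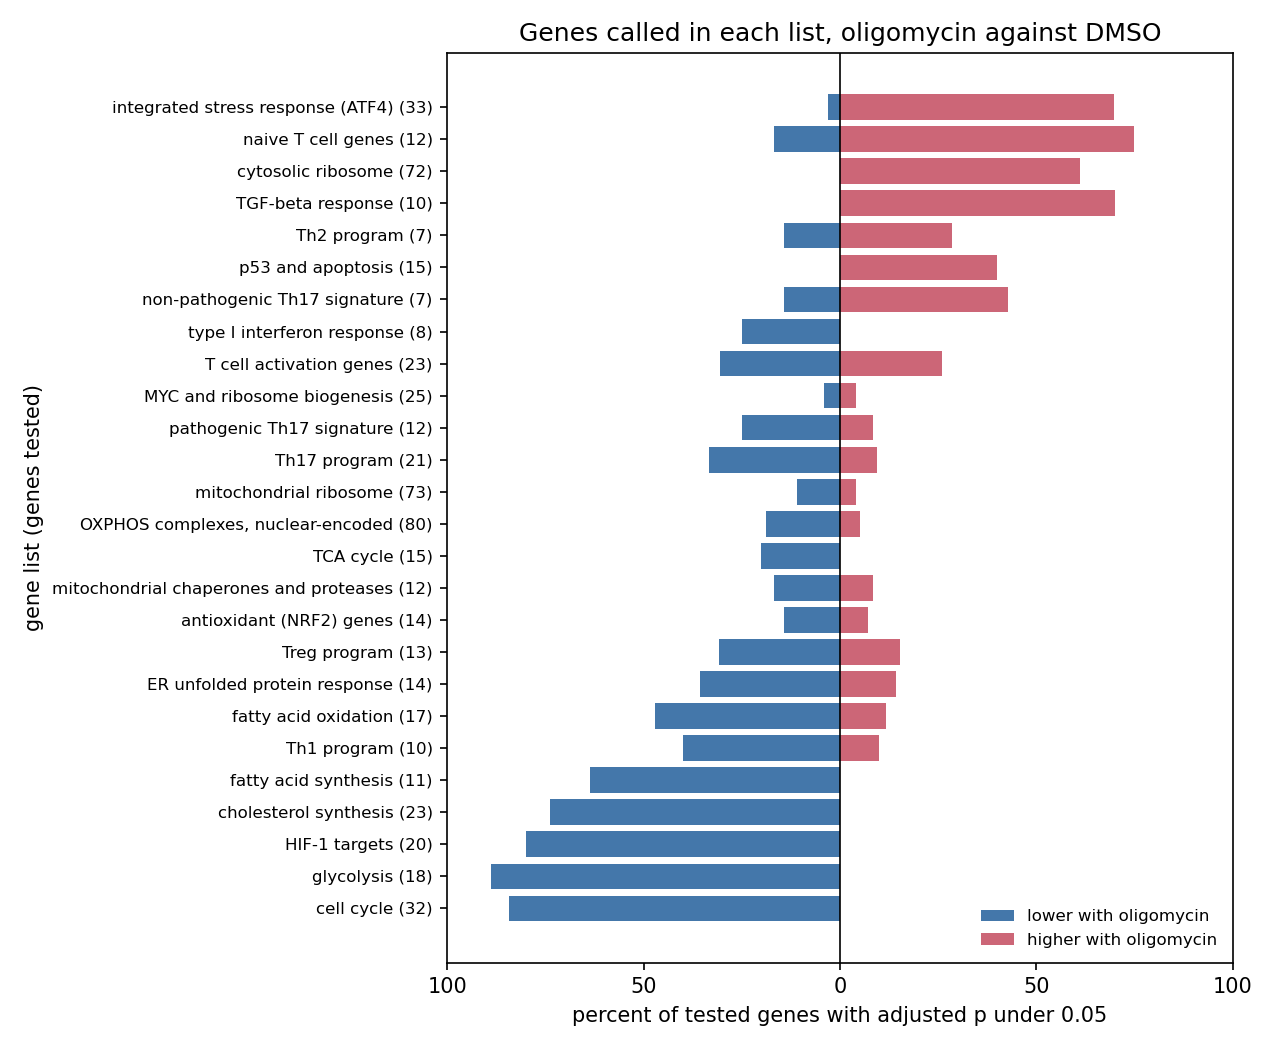
Percent of the tested genes of each of 26 gene lists with an adjusted p under 0.05, lower (left) or higher (right) with oligomycin; the number of tested genes is in parentheses and lists are ordered by median log2 change. In glycolysis 16 of 18 genes were lower, and in the integrated stress response 23 of 33 were higher.

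Targets of ATF4, the transcription factor of the integrated stress response, which raises amino acid synthesis and uptake, were higher with oligomycin. In this list 23 of 33 genes rose and 1 fell, also when adjusted over the list alone. The median log2 change was 0.72 (camera adjusted p = 1.96e-10, and adjusted p = 0.336 with an estimated correlation). Slc7a3, an arginine and lysine transporter, rose from 3.55 ± 0.428 to 34.9 ± 9.86 FPKM (log2 change 2.95, SE 0.19, adjusted p = 4.46e-05). Cth, which makes cysteine from cystathionine, rose from 5.04 ± 0.613 to 32.2 ± 6.52 FPKM (adjusted p = 4.46e-05). Trib3, a pseudokinase, and Atf5, a related transcription factor, had means 5.86-fold and 5.77-fold higher, and Ddit3, the gene of the stress factor CHOP, one 4.01-fold higher. Atf4 itself rose by 0.57 (adjusted p = 0.0122), a call lost without DMSO replicate 1 (adjusted p = 0.0542) or DMSO replicate 3 (0.054). The gene that fell was Vldlr, a lipoprotein receptor, from 1.52 to 0.333 FPKM, which was too low to be tested without any 1 of the DMSO libraries.

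Among 15 genes of the p53 and apoptosis list 6 rose and 0 fell, also when adjusted over the list alone. The median log2 change was 0.34 (camera adjusted p = 0.0261, and adjusted p = 0.502 with an estimated correlation), and the call was lost without oligomycin replicate 3 (adjusted p = 0.0556). Bbc3, the gene of the death-promoting protein PUMA, rose from 5.04 ± 0.120 to 21.6 ± 5.09 FPKM (log2 change 1.88, SE 0.17, adjusted p = 0.000148). Btg2, Aen and Phlda3, which are induced by p53, rose by 0.75, 0.72 and 0.68.

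Other stress programs did not pass camera. Of 14 genes of the unfolded protein response of the endoplasmic reticulum 2 rose and 5 fell (3 and 7 adjusted over the list alone; camera adjusted p = 0.212). Herpud1 and Sel1l, which act in the degradation of misfolded proteins, rose, with means 1.70-fold and 1.52-fold higher. The chaperone gene Sdf2l1 fell from 98.4 ± 5.16 to 42.5 ± 4.28 FPKM (adjusted p = 0.000268), and Hsp90b1, Manf, Pdia6 and Xbp1, the gene of a transcription factor of this response, fell by 0.79, 0.71, 0.65 and 0.43. Pdia6 was not called without DMSO replicate 1 (adjusted p = 0.0666) or oligomycin replicate 3 (0.0618), nor Xbp1 without any library other than oligomycin replicate 1 (between 0.066 and 0.109). In this list 3 genes fell without DMSO replicate 1 or oligomycin replicate 3 and 8 without oligomycin replicate 1. Of 12 genes for mitochondrial chaperones and proteases 1 rose (Dnaja3) and 2 fell (Htra2 and Clpx), against 1 and 3 adjusted over the list alone (camera adjusted p = 0.293, though fry called this list lower at adjusted p = 0.0393). Htra2, a protease of the intermembrane space, fell from 30.1 ± 2.54 to 14.4 ± 1.41 FPKM (adjusted p = 0.000687), whereas Dnaja3 and Clpx were not called without any 1 of the libraries (adjusted p between 0.0662 and 0.16 and between 0.0518 and 0.124).

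Among 14 antioxidant targets of NRF2, 1 rose (Gclc, of glutathione synthesis) and 2 fell (Gpx1, a glutathione peroxidase, and Txn1, thioredoxin), also when adjusted over the list alone (camera adjusted p = 0.212). Gclc was not called without DMSO replicate 1 or 3 or oligomycin replicate 2 or 3 (adjusted p = 0.126, 0.0943, 0.0706 and 0.116) and Gpx1 without DMSO replicate 2 or 3 (0.0514 and 0.058). Txn1 was not called without any library other than oligomycin replicate 1 (between 0.0658 and 0.0973), where 5 genes fell. Of 8 type I interferon response genes Gbp2 and Zbp1, both interferon-induced, fell and 0 rose, also when adjusted over the list alone. The median was 0.05, the mean -0.17 and the camera test pointed down (adjusted p = 0.851); without oligomycin replicate 2 the median was -0.07. Gbp2, a guanylate-binding protein, fell from 151 ± 4.29 to 56.2 ± 12.2 FPKM (adjusted p = 0.000471), and Zbp1 was not called without DMSO replicate 1 (adjusted p = 0.0566) or oligomycin replicate 3 (0.0533).

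Transcripts of dividing cells were lower with oligomycin. In the cell cycle list 27 of 32 genes fell and 0 rose (29 and 0 adjusted over the list alone). The median log2 change was -1.56 (camera adjusted p = 7.3e-17, and adjusted p = 0.336 with an estimated correlation). Cdc20, which activates the anaphase-promoting complex, fell from 95.6 ± 7.12 to 20.9 ± 0.410 FPKM (adjusted p = 2.64e-05). The mitotic kinases Aurka and Plk1 and the mitotic cyclin gene Ccnb1 fell by 1.93, 2.19 and 2.24. Mki67 and Top2a, general markers of proliferation, had means 3.10-fold and 3.04-fold lower. Among the MYC targets of ribosome biogenesis 1 of 25 rose (Rrp9) and 1 fell (Odc1), and 0 and 0 when adjusted over the list alone. Rrp9 was not called without any library other than oligomycin replicate 2 (adjusted p between 0.0641 and 0.142), nor Odc1 without any other than oligomycin replicate 1 (between 0.0539 and 0.0992). Rrp9 also lost its call with the column number as a block (adjusted p = 0.0509) and Odc1 under quantile normalization (0.0506). The median of that list was 0.01, its mean -0.02 and the camera test pointed up (adjusted p = 0.832), and without oligomycin replicate 1 the median was -0.08 and 4 genes fell. Myc, the gene of the growth-promoting transcription factor, stood at 56.0 ± 8.19 and 49.7 ± 8.14 FPKM (adjusted p = 0.435).

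Genes for proteins of the cytosolic ribosome rose together. Of 72 such genes 44 rose and 0 fell (47 and 2 adjusted over the list alone), and 27 rose without DMSO replicate 3 and 3 fell without oligomycin replicate 1. The median log2 change was 0.60 (camera adjusted p = 1.57e-10, and adjusted p = 0.278 with an estimated correlation). Rps24 rose from 221 ± 4.23 to 494 ± 20.3 FPKM (SE of the log2 change 0.12, adjusted p = 0.000327), and Rps15a, Rps19 and Rps10 had means 2.15-fold, 2.14-fold and 1.92-fold higher. Because these genes have many near-identical pseudogenes, their single values are uncertain.

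**Figure D3:**
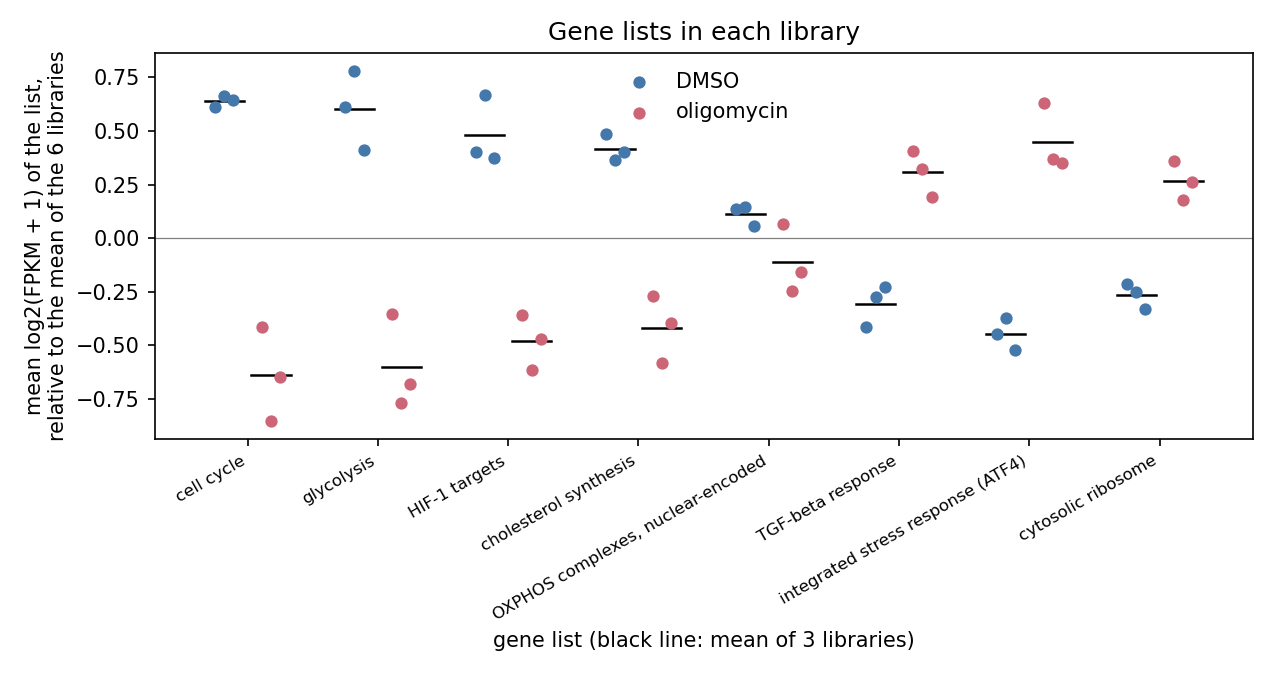
Mean log2(FPKM + 1) of the genes of 8 lists in each library, relative to the mean of the 6 libraries; points are libraries and black lines the means of 3 libraries. The cell cycle list lay between 0.61 and 0.66 with DMSO and between -0.86 and -0.41 with oligomycin.

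Genes of resting T cells were mostly higher. In the list of naive T cell genes 9 of 12 rose and 2 fell, also when adjusted over the list alone. The median log2 change was 0.72 (camera adjusted p = 0.013, and adjusted p = 0.341 with an estimated correlation). Klf2, a factor of T cell quiescence (XLOC_019970, chromosome 8, 72319062 to 72321654), rose from 4.88 ± 2.02 to 48.4 ± 19.7 FPKM (log2 change 3.06, SE 0.34, adjusted p = 0.000497). Its target S1pr1, a receptor for exit from lymph nodes, rose from 21.8 ± 2.44 to 80.3 ± 26.8 FPKM (adjusted p = 0.000994). Bach2, a repressor of effector programs, and Tcf7, a factor of naive and memory cells, rose too, with means 1.79-fold and 2.35-fold higher. Satb1, a chromatin organizer, fell from 162 ± 33.8 to 56.8 ± 3.71 FPKM (adjusted p = 0.000381), and Id3, an inhibitor of E proteins, by 0.66. Id3 was not called without DMSO replicate 1 (adjusted p = 0.107), DMSO replicate 3 (0.0683) or oligomycin replicate 1 (0.0677), which left 1 falling gene.

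Of 23 genes induced on T cell activation 6 rose and 7 fell (7 and 7 adjusted over the list alone). Cd69, an early activation antigen, rose from 36.6 ± 1.08 to 104 ± 6.63 FPKM (adjusted p = 6.82e-05) and Egr2, a transcription factor induced by the T cell receptor, by 1.00. Tnfrsf9, the costimulatory receptor 4-1BB, fell from 134 ± 49.8 to 8.69 ± 3.26 FPKM (adjusted p = 8.68e-05). The median was 0.03, the mean -0.20 and the camera test pointed down (adjusted p = 0.901). The median turned to -0.03 under quantile normalization, -0.01 without DMSO replicate 1 and -0.12 without oligomycin replicate 2. In the TGF-β response list 7 of 10 genes rose and 0 fell (8 and 0 adjusted over the list alone), and 4 rose without DMSO replicate 1 or DMSO replicate 3. The median there was 0.48 (camera adjusted p = 0.000319, and adjusted p = 0.278 with an estimated correlation). Smad7, an inhibitor of the pathway, rose from 16.1 ± 2.25 to 43.4 ± 6.66 FPKM (adjusted p = 0.000466) and Tgfbr1, a receptor, from 24.6 ± 5.32 to 61.5 ± 9.92 (adjusted p = 0.00141).

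Several of the 12 largest falls and 12 largest rises belonged to none of these lists. Cysltr1 and Ltb4r1, receptors for leukotrienes, fell by 3.69 and 3.54, to 2.05 ± 0.698 and 0.802 ± 0.262 FPKM. Plac8 fell by 3.05 and Mgarp, a mitochondrial protein, by 2.97. LOC100302567, which shares its locus with another row, had 161, 139 and 89.9 FPKM with DMSO and 83.1, 0 and 0 with oligomycin (adjusted p = 0.0373). Its call was lost without DMSO replicate 1, 2 or 3 (adjusted p = 0.0945, 0.0806 and 0.0745) and without oligomycin replicate 2 or 3 (0.0909 and 0.118). The microRNA row Mir324, which also shares its locus with another row, was listed at 0 in the DMSO libraries and at 181, 323 and 147 FPKM in the oligomycin libraries (adjusted p = 2.39e-06). Cox6a2, a cytochrome c oxidase subunit typical of muscle, rose from 0.315 ± 0.125 to 9.81 ± 2.0 FPKM (adjusted p = 3.59e-05). Atp1b1, a subunit of the sodium pump whose row shares its locus with another, rose from 4.06 ± 1.43 to 36 ± 7.09 FPKM (adjusted p = 7.23e-05). Ms4a4b rose from 2.08 ± 0.403 to 19.8 ± 8.57 FPKM. Ccl1, a chemokine, Cyp1a1, a target of the aryl hydrocarbon receptor, and Avil, an actin-binding protein, rose from under 1 FPKM in each DMSO library to 9.16 ± 7.27, 6.99 ± 2.40 and 5.91 ± 0.758.

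Markers of other cells were few in the table. Of 4 tested myeloid and dendritic cell markers 1 fell and 0 rose (1 and 1 adjusted over the list alone). H2-Ab1, a class II MHC chain, went from 21.9 ± 4.58 to 1.70 ± 0.919 FPKM (adjusted p = 0.000104), while H2-Aa stood at 1.46 ± 1.21 and 2.46 ± 1.75 (adjusted p = 0.404). H2-Ab1 was the 1 gene that fell in the family of MHC genes, in which 6 of 17 rose, other class II genes among them. The family was taken by its H2 symbols, and the genes that rose include H2-Ke6, which does not encode an MHC chain. That family did not pass for rises in Fisher's exact test (adjusted p = 0.0602). Cst3, a protease inhibitor, stood at 83.7 ± 14.4 and 64.0 ± 11 FPKM (adjusted p = 0.123). It was called lower without oligomycin replicate 1 (adjusted p = 0.0436) and with the column number as a block (0.0457). Cd68, a lysosomal protein, stood at 1.43 ± 0.551 and 3.30 ± 1.53 FPKM (adjusted p = 0.0532) but was called higher without oligomycin replicate 1 (0.0466). Of 4 markers of CD8 T cells and NK cells 1 rose and 0 fell (0 and 0 adjusted over the list alone). Nkg7, a granule protein, went from 2.01 ± 0.934 to 4.26 ± 1.21 FPKM (adjusted p = 0.0499). Its call was lost without DMSO replicate 2 (adjusted p = 0.0698), DMSO replicate 3 (0.14), oligomycin replicate 1 (0.0987) or oligomycin replicate 2 (0.124). With all libraries it was lost with a pseudocount of 0.1 (0.0612), no filter (0.0565), quantile normalization (0.0667) or no intensity trend (0.0503). Klrd1, a receptor chain of NK cells, stood at 26.2 ± 11.8 and 16.3 ± 9.56 FPKM (adjusted p = 0.3). It was called lower only with the column number as a block (adjusted p = 0.00758). Cd8b1, a chain of the CD8 coreceptor, stood at 2.83 ± 0.257 and 2.90 ± 0.453 FPKM (adjusted p = 0.927). Lists of B cell, γδ T cell, and erythroid and platelet markers are not analysed here, nor is the list of mitochondrially encoded OXPHOS genes.

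Of the 26 lists tested, 14 passed camera with the preset correlation, 5 upward and 9 downward, and 0 of these calls held with an estimated correlation. Fry called 12 of the 14, but neither the OXPHOS complexes (adjusted p = 0.114) nor the mitochondrial ribosome (0.184). In addition it called the Th17 list (0.0245), the Th1 list (0.0457) and the mitochondrial chaperones (0.0393), all lower. The other 9 ways to split the 6 libraries into 3 and 3 gave at most 3 called genes but up to 17 called lists. Each of them set 2 libraries of 1 group and 1 of the other against the rest. The group difference then widens the spread on each side, which keeps gene calls few, and part of it remains between the sides. Neither count therefore gauges how many calls are false.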

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

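Tests with the column number as a block, without small RNA rows, without rows that share a locus or name several genes, with equal FPKM sums and of lists without cell cycle and histone rows were chosen only after the result was seen. Outside the settings that leave out a library, 2458 to 3532 genes were called (3013 as reported), and 11 to 15 lists (14 as reported) except with an estimated correlation, where camera called 0. Under median-ratio rescaling, quantile normalization and equal FPKM sums the median log2 change of all genes was 0.00234, 0.0313 and 0.0104 (-0.00442 as reported). Of 137 named genes that were called, 112 passed the threshold in every alternative that tested them and 25 lost it in at least 1, and of 19 not called 9 passed it in at least 1; none of the called genes changed direction. Of 14 called lists 9 kept their calls in every alternative but the estimated correlation, and the Th17 list, not called as reported, passed without small RNA rows (adjusted p = 0.041) and without cell cycle and histone rows (0.0469), in a range over its alternatives from 0.0104 to 0.397. With all libraries, Txn1, Xbp1 and Clpx were among those that lost their calls under quantile normalization (adjusted p = 0.0691, 0.0875 and 0.0549). Atp5l lost it with no filter (0.0511) or no intensity trend (0.0559), and Dnaja3 with no intensity trend (0.0625). The direction turned for values that were not called. With a minimum of 5 FPKM the median log2 change was 0.026 in the Th17 list and 0.083 in the pathogenic signature, and under quantile normalization it was -0.028 in the T cell activation list and the log2 change of Cd8b1 was -0.041. The minimum leaves the log2 change of each gene as it was, so these medians of the Th17 and pathogenic lists turned because members with low values left the lists. The cause of the turns under quantile normalization was not tested. Leaving out 1 library at a time gave 1769 to 3248 called genes (780 to 1387 higher, 989 to 1861 lower) and 11 to 15 called lists. Log2 changes then ran from -0.14 to 0.18 for Batf, from -0.12 to 0.39 for Il10 and from -0.053 to 0.11 for Cd8b1. List medians ran from -0.23 to 0.012 for Th17, from -0.28 to 0.061 for the pathogenic and from -0.074 to 0.39 for the non-pathogenic signature, from -0.50 to 0.20 for Th2, from -0.12 to 0.10 for T cell activation, from -0.076 to 0.071 for MYC and from -0.073 to 0.18 for type I interferon. 13 named genes were too low to be tested without 1 or more of the libraries. Areg of the Th2 list and Il23r of the Th17 list were among them, so part of these ranges comes from lists that lacked a member. The sample titles share the numbers 17, 42 and 43 between the groups, but the columns carry only 1 to 3. With the column number as a block 3532 genes were called, 2951 of them shared with the calls reported. Klrd1, Idh3a, Stat6, Lonp1 and Cst3 were then called lower (adjusted p = 0.00758, 0.0197, 0.0311, 0.032 and 0.0457), Rrp9 was not called (0.0509), and no other call of a named gene or a list changed. The libraries of like number were not treated as pairs, because the deviations from the group mean correlated at 0.056, 0.247 and 0.132 between them, not all above the bound of 0.1 set beforehand, and 5 of 6 libraries correlated best with their own number. Without small RNA rows, a choice made after the values were seen, those correlations were 0.201, 0.358 and 0.136 and 6 of 6 did so, so the answer turns on these rows and a pairing by column number stays open. Depth is unknown, so what it limits could not be assessed.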

Other observations

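Tests of gene families, histone reads, scaling, mRNAs with a terminal oligopyrimidine tract, activation, MYC, poly(A) capture, shared histone reads and S phase were chosen only after the result was seen. Among 14 gene families with 28 Fisher's exact tests (2-sided, adjusted together), histone genes had the largest share of falls. The test takes genes as independent, which members of a family that share reads or are regulated together are not. The p-values of all families may therefore be too small, and they do not measure the spread between libraries. Of 55 histone genes, which package newly made DNA, 51 fell and 1 rose, against 16.1% and 14% of all tested genes (median log2 change -1.73, adjusted p = 9.48e-35 for the falls). Histone rows took 10.3%, 9.09% and 9.41% of the FPKM outside small RNA rows with DMSO and 3.64%, 2.98% and 3.40% with oligomycin. The gene that rose was Hist2h2be, from 1.57 ± 0.421 to 3.59 ± 0.903 FPKM (adjusted p = 0.0179), a call lost without DMSO replicate 2 (adjusted p = 0.0612), DMSO replicate 3 (0.0537) or oligomycin replicate 3 (0.0645). Genes of centromere proteins, on which chromosomes attach to the spindle, fell in 13 of 18 cases (adjusted p = 1.71e-06), and those of kinesins, motor proteins of which many act in mitosis, in 12 of 24 (adjusted p = 0.000669). Their medians, -0.82 and -0.62, stayed below 0 under each of the 3 scalings.

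Zinc finger genes of the Zfp series, most of which encode DNA-binding proteins, fell more rarely than other genes. Of 252 tested, 6 fell (adjusted p = 1.47e-11) and 62 rose (adjusted p = 3.9e-05), with a median log2 change of 0.25. The excess of rises was lost without DMSO replicates 1, 2 and 3 (27, 33 and 27 rose, adjusted p = 0.348, 0.206 and 0.244) and without oligomycin replicates 2 and 3 (35 and 27 rose, adjusted p = 0.134 and 0.691). The number that fell was 2, 3 and 3 without DMSO replicates 1, 2 and 3 and 3 without oligomycin replicate 2 or 3. Tubulins and serpins passed for falls, snoRNA host genes for rises and proteasome subunits for few rises (adjusted p = 0.038, 0.0438, 0.038 and 0.0286), but these calls were lost without DMSO replicate 2 (0.0944, 0.161, 0.206 and 0.146) and without further single libraries, with a highest adjusted p of 0.0944, 0.263, 0.607 and 0.268. The snoRNA host call was also lost under median-ratio rescaling (0.136) and equal FPKM sums (0.122). The serpin call was lost under median-ratio rescaling (0.0501) and the proteasome call under quantile normalization (0.0586). Of 37 proteasome genes 7 fell with all libraries, but 17 without oligomycin replicate 1 (adjusted p = 0.0008). Only 3, 3 and 2 fell without DMSO replicates 1, 2 and 3, and 3 and 2 without oligomycin replicates 2 and 3. Of the other 6 families none passed with all libraries (lowest adjusted p 0.0602). The MHC family, which holds H2-Ke6 as well, passed for rises without DMSO replicate 2 (0.00418), DMSO replicate 3 (0.0392), oligomycin replicate 1 (0.0156) or oligomycin replicate 3 (0.0168). It also did so under quantile normalization (0.0296). Krüppel-like factors did so without DMSO replicate 2 (0.0325), oligomycin replicate 2 (0.0455) or oligomycin replicate 3 (0.0243).

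Ribosomal protein genes rose together, with a median log2 change of 0.60, and reads shared with pseudogenes were not tested for them and stay open. Transcript length or GC content as the whole cause was argued against by 293 other genes matched on both to 71 of the 72, whose median was -0.12 (-0.22 to 0.000843 over the 9 pairings of a DMSO with an oligomycin library). A share of reads freed by the histone genes would lift all other genes alike, but the median of the ribosomal protein genes lay 0.61 above that of 9702 other genes (0.50 to 0.75). The authors' scaling between libraries as the whole cause was argued against by 3 rescalings, under which the median of the ribosomal protein genes was at least 0.61 (0.49 to 0.81 over the pairings), with 41 to 44 rising. A candidate explanation is a rise of the class of mRNAs with a terminal oligopyrimidine tract, since 15 other such mRNAs had a median of 0.41 (0.22 to 0.64), with 7 rising and 1 falling (3 rising without DMSO replicate 1 and 2 without DMSO replicate 3).

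Glycolysis genes and HIF-1 targets fell together. Lower MYC activity across its targets, as the whole cause, was argued against by the list of MYC targets of ribosome biogenesis. Its median was 0.006576 (-0.13 to 0.26), and its members had an SD of 0.27. These targets cannot show whether MYC acted less on the glycolysis genes alone. Lower HIF-1 activity may account for part of the pattern. The 14 other hypoxia-inducible genes had a median of -0.37 (-0.57 to -0.08), with 5 falling, 0 rising and the rest not called. That fall is smaller than the medians of the glycolysis and HIF-1 lists (-1.07 and -0.95). The bounds also differed: a median below 0 in each pairing was asked here, but -0.5 or lower for MYC and activation. More unactivated cells cannot be told apart from lower HIF-1 activity. The list of genes induced on activation had a median of 0.032 (-0.20 to 0.16) over members that went both ways (6 rose, 7 fell, SD 1.1). Besides, 9 of 12 naive T cell genes rose. The direct effect of blocked oxidative phosphorylation, which the design names, stays open and was not tested apart from these.

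Histone and cell cycle transcripts fell together. Reads shared between near-identical histone genes would leave their sum unchanged, but the log2 change of the summed histone FPKM was -1.63 (-1.93 to -1.37). For the histone part, poorer capture of RNA without a poly(A) tail, which mRNAs of the cell cycle list carry, cannot be told apart. The 86 small RNA rows other than microRNAs had a median of 0.18 (-0.07 to 0.61) over members that spread widely (5 rose, 1 fell, SD 1.7). These rows can also hold reads of host transcripts. Leaving out 1 library moved their median between 0.043 and 0.30. Without DMSO replicate 1 or oligomycin replicate 3, 2 rose and 2 fell. Without DMSO replicate 3, 3 rose, and without oligomycin replicate 1, 8 rose. Fewer cells in S phase may account for part of the pattern, since 36 replication genes outside the list had a median of -0.59 (-0.79 to -0.31), with 24 falling and 1 rising (15 falling without DMSO replicate 2 and 13 without DMSO replicate 3, and 0 rising in the limma test without any library other than oligomycin replicate 2). Of the S phase and M phase genes, 11 of 16 and 16 of 16 fell (6 of the S phase genes without DMSO replicate 3 and 7 without oligomycin replicate 3). The M phase genes fell further, with a median of -1.89 (-2.14 to -1.65), against -0.62 (-0.91 to -0.28) for the S phase genes. Fewer cells in mitosis were not tested and stay open.

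Counting the real one, 1 of the 10 splits of the 6 libraries into 3 and 3 gave as many called genes (3013, with 3 as the highest other). As many called lists came from 2, the real one included (14, with 17 as the highest other). The other splits mix both groups on each side, so they cannot gauge how many calls are false. 10 splits are too few for a share under 0.05.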
